A study of Mus musculus with 25 samples.

How the data were processed

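Total RNA from cryo-homogenized mammary tumors and reference glands was amplified from 100 ng of input with a whole-transcript kit, labelled and hybridised to Affymetrix arrays, per the labels' protocols. The values analysed are the deposited table of 25 arrays by 34760 probe sets, on a log2 scale by their range of 4.13 to 13.9, a base that the labels do not state. The submitters' processing notes name the affy package without a version, and the steps of background correction and summarization are not given in the sources used here. Scanner files were not used here, so those steps could not be varied. A genome build is not given in the sources used here and no coordinates are printed.

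Each column of the table carries the identifier of 1 sample, and columns were joined to labels by that identifier. The arrays were grouped by title into 10 K8 tumors, 10 Lgr5 tumors, 3 Lgr5 glands and 2 K8 glands before the data were examined, and these groups were kept although tissue markers went against the labels of several arrays. The values of several arrays may therefore belong to other samples than their labels name. No sample was moved to another group, and no comparison was run on an order of samples other than the labelled one.

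Probe sets were named from the platform annotation: 21640 had 1 gene symbol, 1321 had several and 11799 were unlisted. Of those with 1 symbol, 21553 matched a gene identifier in the GRCm38.p6 gene table, which changed 0 symbols. For 954 symbols with more than 1 probe set the brightest over all arrays was used, giving 19937 genes tested. No arrays held identical values (highest correlation 0.995 over all probe sets and 0.996 over the genes tested).

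Gene tests used limma 3.58.1 in R 4.3.3: lmFit on the means of 4 groups over all 25 arrays, eBayes without trend or robust settings, and Benjamini-Hochberg adjustment with a threshold of 0.05, counted also with a log2 difference of at least 1. Errors beside log2 differences are SEs from this fit. The 5 contrasts were each tumor group against the gland group of its line, tumor against tumor, gland against gland, and the difference of the tumor-gland contrasts. All these choices and the alternatives in the closing section, except those said there to be added later, were made before the data were examined.

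Gene lists (25 lists with 430 genes, of which 400 were measured as single-symbol probe sets and the others were not analysed here) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. No list call held with an estimated correlation in any contrast. Adjusted over the list alone, adipocyte genes passing numbered 18 of 19 in the Lgr5 tumor-gland contrast, squamous genes 16 of 23, cell cycle genes 29 of 29 and epithelial genes 13 of 18. The same counts were 17 of 23 squamous, 9 of 19 basal, 7 higher and 1 lower of 11 hormone-sensing and 16 of 20 fibroblast genes in the K8 tumor-gland contrast, and 19 of 19 adipocyte, 29 of 29 cell cycle and 16 of 18 epithelial genes between tumors. The spread among tumors was tested with 100000 permutations of the line labels.

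Genes were named in the text by a rule set beforehand, from which the text draws: 8 genes the design is about, the 10 highest and 10 lowest log2 differences past the threshold in each contrast without predicted genes, RNA genes and receptor or immunoglobulin segments, and the 4 members of each list with the smallest adjusted p. Figures were drawn with matplotlib 3.10.9.

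The gene test was tested on simulated data with 100 genes changed by 1 and 100 by 2 on the log2 scale among 19937. It recovered 83% and 96% for Lgr5 tumors against Lgr5 glands, 77% and 91% for K8 tumors against K8 glands, 93% and 96% for tumors against tumors, 71% and 85% for glands against glands and 77% and 83% for the difference of contrasts. It made 5 to 9 false calls per contrast. The simulated noise was independent between genes, unlike that of the real arrays, so these rates may not hold for the real data.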

Results

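Gene expression was measured on 25 single-colour Affymetrix whole-transcript arrays from mouse mammary tissue. The arrays are labelled as 10 tumors from K8-creERT2/PIK3CA H1047R mice, 10 tumors from Lgr5-creERT2/PIK3CA H1047R mice, 3 reference glands from Lgr5-creERT2 control mice and 2 reference glands from K8-creERT2 control mice. In these mice tamoxifen, given at 7 to 8 weeks of age, turns on a mutant form of the PI3-kinase subunit PIK3CA in cells that express keratin 8, a luminal keratin, or Lgr5, a Wnt-responsive receptor. The K8 line has a mixed FVB/CD1 background and the Lgr5 line a mixed FVB/C57/BL6 background, so line and background go together in every comparison between lines. The number of arrays limits the precision, and the array medians lay between 6.34 and 6.43 on the log2 scale. The labels do not say whether tumors of a line came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

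The expression of tissue markers went against the tumor and gland labels of several arrays, and for that reason groups are called by their labels throughout. The mean of 19 adipocyte genes was 12.59 to 12.72 (log2) in the arrays labelled Lgr5 tumors 2, 6, 7, 8 and 9, and at most 11.44 in the other 15 arrays labelled tumor. In the 5 arrays labelled gland, a tissue embedded in fat, it was 7.91 to 9.90. The mean of 29 cell cycle genes was 6.96 to 7.94 in those 5 arrays labelled Lgr5 tumor and 9.13 to 9.68 in the arrays labelled gland. Each direction given below is therefore a direction between sets of labelled arrays, and it does not establish a direction between tumor and gland.

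**Figure D1:**
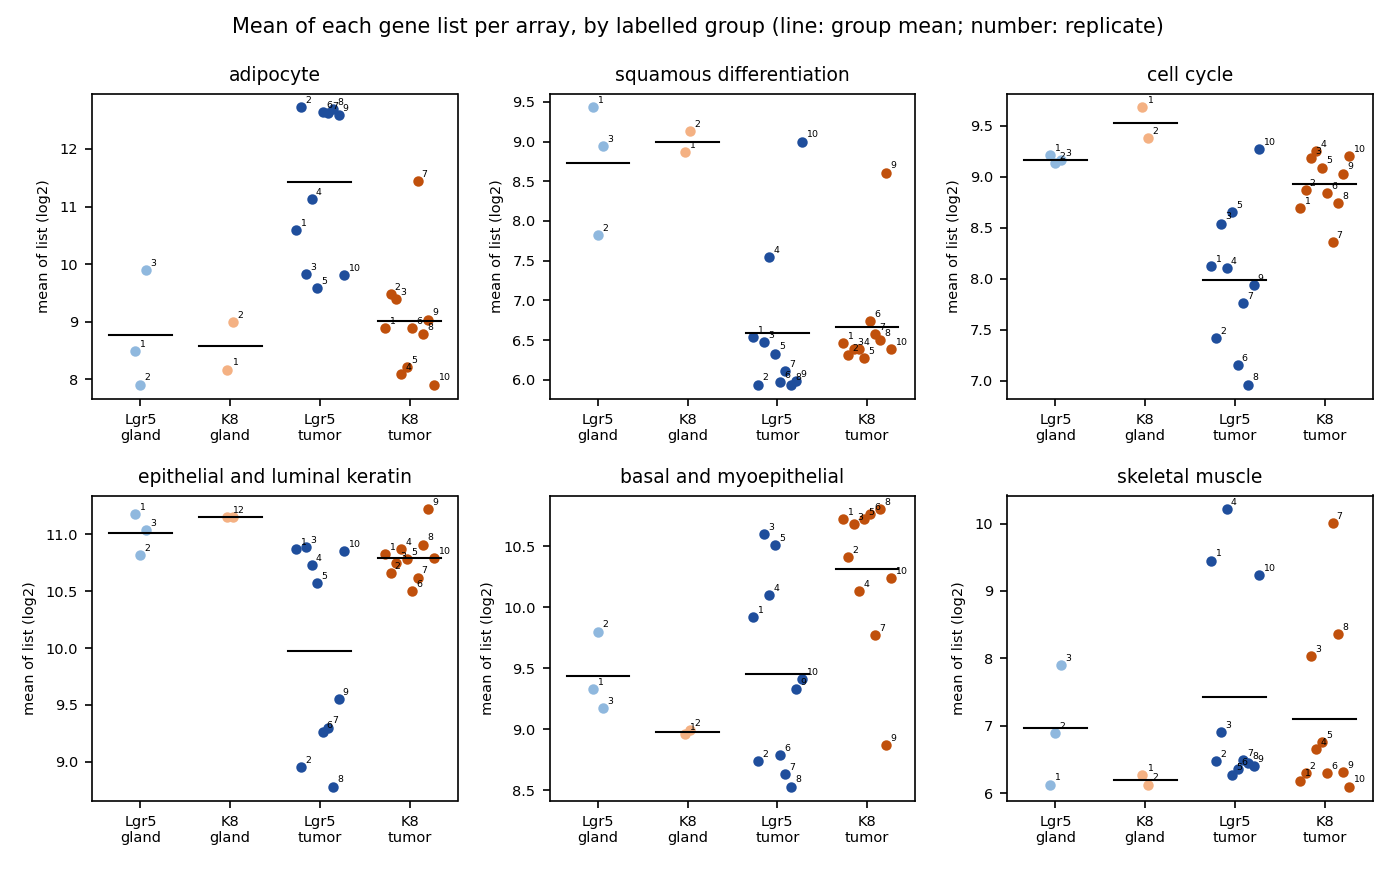
Mean log2 expression of 6 gene lists (vertical axes) in each of the 25 arrays, by labelled group (horizontal axes). Points are arrays with their replicate numbers and lines are group means. The arrays labelled Lgr5 tumors 2, 6, 7, 8 and 9 lie at 12.59 or above for adipocyte genes, while the arrays labelled gland lie at 9.90 or below.

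Pik3ca, the gene whose mutant form the lines carry, did not pass the test in any contrast, with a log2 difference of 0.14 ± 0.07 (SE; limma adjusted p = 0.15) for arrays labelled Lgr5 tumor against Lgr5 gland and 0.16 ± 0.08 (limma adjusted p = 0.225) for K8 tumor against K8 gland. The array does not separate the mutant transcript from the endogenous one. Lgr5 differed by -1.12 ± 0.78 (limma adjusted p = 0.344) in the first contrast and by -2.20 ± 0.91 (limma adjusted p = 0.132) in the second, and neither passed.

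**Figure D2:**
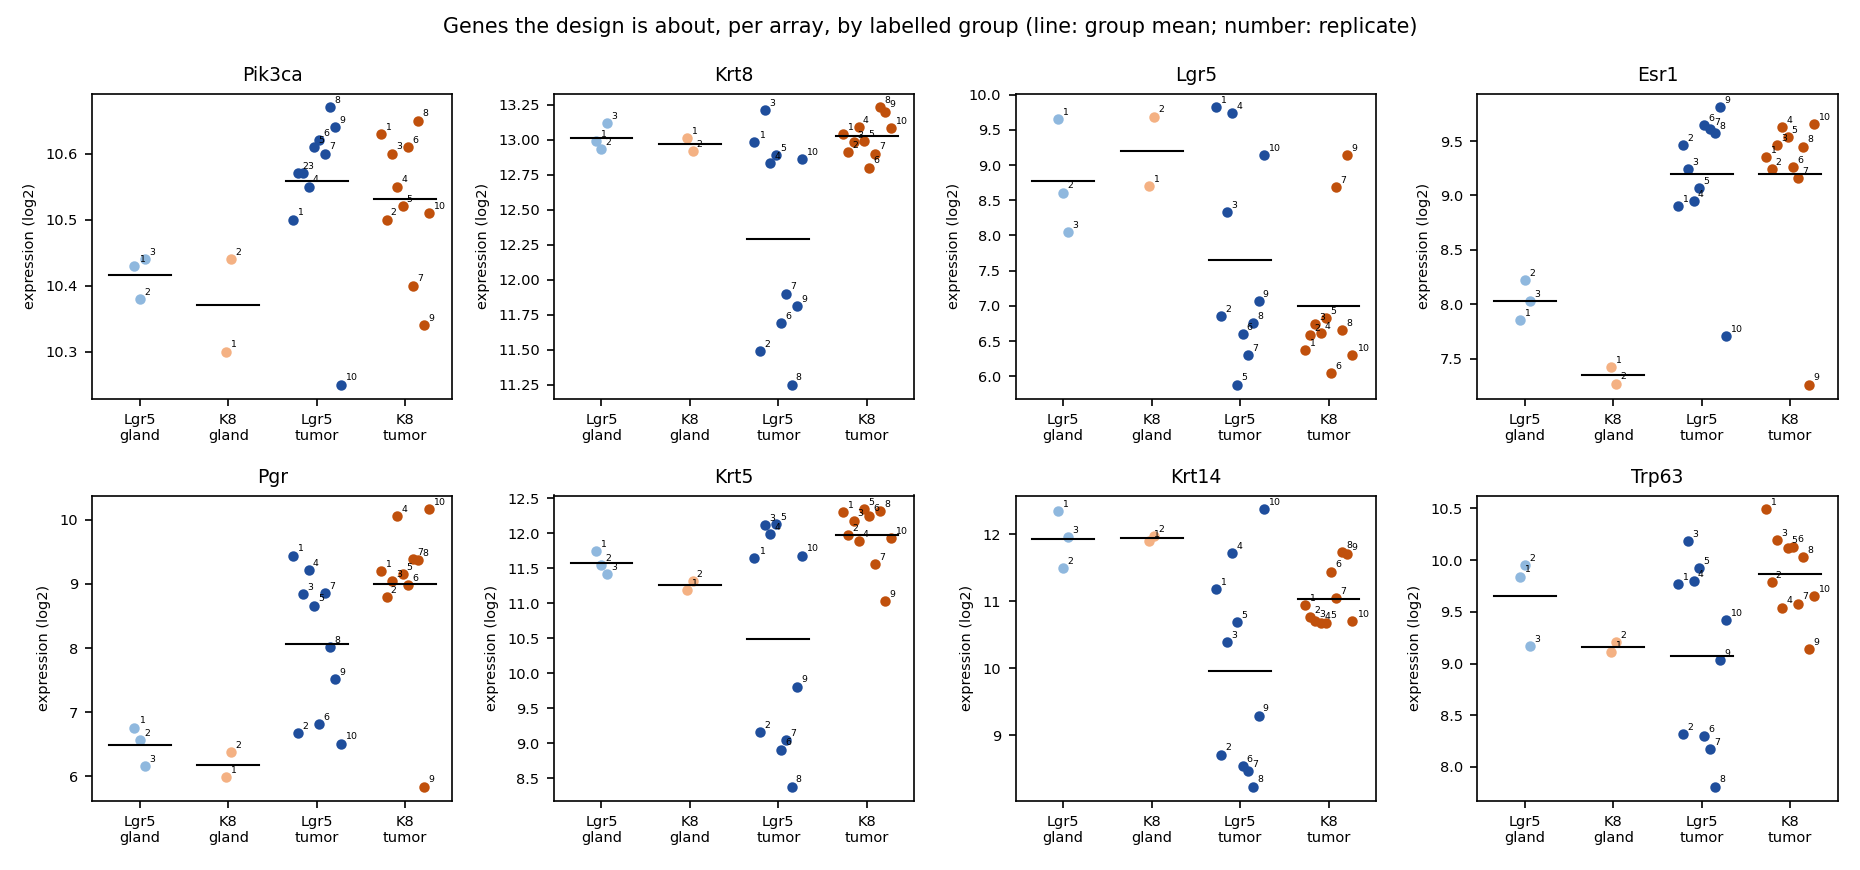
Log2 expression (vertical axes) of 8 genes the design is about in each array, by labelled group (horizontal axes). Points are arrays with their replicate numbers and lines are group means. Esr1 averaged 9.20 in both sets of arrays labelled tumor, 8.03 in those labelled Lgr5 gland and 7.34 in those labelled K8 gland.

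The first comparison asks how tumors of the Lgr5 line differ from reference glands of that line. Adipocyte genes were higher in the arrays labelled Lgr5 tumor (n = 10) than in those labelled Lgr5 gland (n = 3): 16 of 19 rose and 3 did not pass. Adipoq, which encodes the fat-cell hormone adiponectin, rose by 3.35 ± 1.04 (log2, SE; limma adjusted p = 0.034), and the leptin gene Lep rose by 3.53 ± 1.06, a fold of 11.5. The glycerol channel gene Aqp7 rose by 3.73 ± 1.03, the fatty acid transporter gene Cd36 by 2.96 ± 0.66 and Fabp4 by 2.50 ± 0.56. Outside the list the carboxylesterase gene Ces1d rose by 3.97 ± 1.07. The list shifted up (camera adjusted p = 7.7e-12; adjusted p = 0.37 with an estimated correlation). The rise moves with the 5 arrays at 12.59 or above.

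Genes of squamous differentiation were lower in the arrays labelled Lgr5 tumor, where 15 of 23 fell and 8 did not pass. The kallikrein protease gene Klk7 fell by 4.80 ± 1.32 on the log2 scale, Krtdap fell by 4.33 ± 1.02, the stress keratin gene Krt6b fell by 3.94 ± 0.97 and the cornified envelope gene Sprr1b fell by 3.58 ± 0.68. The squamous list had adjusted p = 4.0e-09 (camera; adjusted p = 0.37 with an estimated correlation). Its mean was 5.94 to 6.11 in the arrays labelled Lgr5 tumors 2, 6, 7, 8 and 9, 6.33 to 9.00 in the other 5 arrays labelled Lgr5 tumor (9.00 in tumor 10) and 7.82 to 9.43 in those labelled Lgr5 gland. Outside the list the related protease gene Klk6 fell by 5.05 ± 1.32. Of the neutrophil genes 8 of 15 fell, among them S100a8 with -3.54 ± 0.89 and the chemokine gene Cxcl2 with -2.22 ± 0.54 (camera adjusted p = 3.1e-06; adjusted p = 0.37 with an estimated correlation). Lgr5 tumor 10 had a neutrophil mean of 7.79, within the range of the Lgr5 glands (6.31 to 8.31).

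Cell cycle genes were lower in the arrays labelled Lgr5 tumor: 24 of 29 fell and 5 did not pass (camera adjusted p = 7.1e-13; adjusted p = 0.37 with an estimated correlation). The replication helicase gene Mcm2 changed by -1.33 ± 0.29, the mitotic kinase gene Aurka by -1.15 ± 0.25 and the nucleotide reductase gene Rrm2 by -1.98 ± 0.44. Of the epithelial and luminal keratin genes 5 of 18 fell, among them the tight junction gene Cldn3 with -1.25 ± 0.36 (camera adjusted p = 1.3e-05; adjusted p = 0.425 with an estimated correlation). The epithelial mean was 8.78 to 9.55 in the arrays labelled Lgr5 tumors 2, 6, 7, 8 and 9, against 10.57 to 10.89 in the other 5 labelled Lgr5 tumor and 10.82 to 11.18 in those labelled Lgr5 gland. The cell cycle mean was 6.96 to 7.94, 8.10 to 9.27 and 9.13 to 9.21 in the same sets. Of the milk and alveolar genes 5 of 18 fell, including the whey protein gene Wap with -2.44 ± 0.65 and the alveolar regulator gene Elf5 with -1.38 ± 0.38 (camera adjusted p = 0.00175; adjusted p = 0.37 with an estimated correlation). Of the glycolysis and hypoxia genes 8 of 20 fell, including Egln3 with -2.32 ± 0.55 and the glucose transporter gene Slc2a1 with -1.54 ± 0.41 (camera adjusted p = 1.6e-04; adjusted p = 0.37 with an estimated correlation).

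Stromal genes were higher in the arrays labelled Lgr5 tumor. Of the fibroblast and matrix genes 13 of 20 rose, among them the decorin gene Dcn with 0.87 ± 0.17 and Col6a1 with 1.17 ± 0.24 (camera adjusted p = 8.7e-11; adjusted p = 0.37 with an estimated correlation). Of the endothelial genes 11 of 16 rose, among them Vwf with 1.06 ± 0.22 and the angiopoietin receptor gene Tek with 1.54 ± 0.43 (camera adjusted p = 5.0e-10; adjusted p = 0.37 with an estimated correlation). The endothelial mean was 9.48 to 9.66 in those 5 arrays, 8.45 to 9.36 in the other 5 labelled Lgr5 tumor and 8.20 to 8.29 in those labelled Lgr5 gland. Of the mesenchymal transition genes 5 of 13 rose, including Vim with 0.50 ± 0.08 and Zeb1 with 1.66 ± 0.31 (camera adjusted p = 1.6e-04; adjusted p = 0.281 with an estimated correlation). The peptidase gene Dpep1 rose by 3.63 ± 0.68, the estrogen receptor gene Esr1 by 1.17 ± 0.39 (limma adjusted p = 0.0451), and the basal keratin gene Krt14 fell by 1.98 ± 0.66 (limma adjusted p = 0.0445). Krt8 (-0.72 ± 0.31), Pgr (1.56 ± 0.68), Krt5 (-1.08 ± 0.67) and Trp63 (-0.58 ± 0.40) did not pass. The T cell (camera adjusted p = 5.3e-04), B and plasma cell (0.00545) and brown adipocyte (0.00604) lists shifted up with 0 members past the gene test (adjusted p = 0.425 with an estimated correlation for each).

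In all, limma called 3168 of 19937 genes at a Benjamini-Hochberg adjusted p under 0.05, 1052 higher and 2116 lower in the arrays labelled Lgr5 tumor, of which 398 and 385 differed by at least 1 on the log2 scale. The count was 690 with only the groups compared, 7815 with array weights, 1737 with the replicate number as a block, and 0 with the adipocyte mean as a covariate (limma; 2998 at an unadjusted p under 0.05). Without the arrays labelled Lgr5 tumors 2, 6, 7, 8 and 9 it was 1, without K8 tumor 9 and Lgr5 tumor 10 it was 5387, without all 7 it was 3582, and without a single array it was 252 (Lgr5 gland 1), 1976 (gland 2), 705 (gland 3) or 4990 (Lgr5 tumor 10).

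The second comparison asks the same of the K8 line. Luminal hormone-sensing genes were higher in the arrays labelled K8 tumor (n = 10) than in those labelled K8 gland (n = 2): 5 of 11 rose, 1 fell and 5 did not pass. Foxa1, a pioneer factor for the estrogen receptor, rose by 3.25 ± 0.88 (log2, SE; limma adjusted p = 0.0278), Cited1 by 3.36 ± 0.88 and Esr1 by 1.86 ± 0.46 (limma adjusted p = 0.02), while Xbp1 fell by 0.97 ± 0.21. The list had camera adjusted p = 1.7e-04 (adjusted p = 0.188 with an estimated correlation). The list mean of K8 tumor 9 was 7.91, below both K8 glands (8.01 and 8.26), and those of the other K8 tumors were 9.44 to 10.15. The progesterone receptor gene Pgr rose by 2.81 ± 0.81 (limma adjusted p = 0.0331).

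Basal and myoepithelial genes were also higher in the arrays labelled K8 tumor, where 7 of 19 rose and 12 did not pass. The contractile genes Cnn1, Myh11 and Acta2 rose by 4.85 ± 1.24, 4.27 ± 1.04 and 1.92 ± 0.48 (camera adjusted p = 1.5e-05; adjusted p = 0.289 with an estimated correlation). The basal mean was 8.87 in K8 tumor 9, at least 9.77 in the other K8 tumors and 8.96 and 8.99 in the K8 glands. The fibrinogen chain gene Fgg rose by 5.07 ± 1.35, a fold of 33.7. Of the fibroblast and matrix genes 10 of 20 rose, among them Dcn with 1.15 ± 0.19 and the lumican gene Lum with 3.01 ± 0.61 (camera adjusted p = 3.2e-12; adjusted p = 0.188 with an estimated correlation). Of the endothelial genes 5 of 16 rose, including Tie1 with 1.13 ± 0.27 (camera adjusted p = 4.9e-09; adjusted p = 0.247 with an estimated correlation). K8 tumor 9 had an endothelial mean of 7.87, the other K8 tumors at least 8.67 and the K8 glands 7.75 and 8.07. Of the mesenchymal transition genes 5 of 13 rose, including Vim with 0.53 ± 0.10 and Zeb1 with 1.41 ± 0.36 (camera adjusted p = 8.3e-06; adjusted p = 0.0883 with an estimated correlation).

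Squamous genes were lower in the arrays labelled K8 tumor, where 14 of 23 fell and 9 did not pass (camera adjusted p = 1.1e-10; adjusted p = 0.247 with an estimated correlation). The squamous mean was 8.61 in K8 tumor 9, 6.27 to 6.74 in the other K8 tumors and 8.87 and 9.13 in the K8 glands. The keratin genes Krt1 and Krt16 fell by 3.16 ± 0.57 and by 3.94 ± 0.93, and Sprr1b fell by 4.01 ± 0.80. Outside that list Crct1 fell by 5.60 ± 1.66 and Klk6 fell by 5.52 ± 1.55. Of the neutrophil genes 5 of 15 fell, including S100a8 with -4.18 ± 1.05 and S100a9 with -3.10 ± 0.79 (camera adjusted p = 2.9e-05; adjusted p = 0.289 with an estimated correlation). Their mean was 6.96 in K8 tumor 9, at most 5.82 in the other K8 tumors and 7.03 and 7.57 in the K8 glands. Of the glycolysis and hypoxia genes 8 of 20 fell, including the lactate transporter gene Slc16a3 with -2.38 ± 0.59 and Ldha with -0.48 ± 0.11 (camera adjusted p = 4.2e-08; adjusted p = 0.201 with an estimated correlation). Their mean was 10.52 in K8 tumor 9, at most 9.85 in the other K8 tumors and 10.58 and 10.85 in the K8 glands. Of the milk and alveolar genes 3 of 18 fell, including Wap with -3.07 ± 0.77 and Olah with -1.97 ± 0.43 (camera adjusted p = 0.00699; adjusted p = 0.401 with an estimated correlation), and of the cholesterol synthesis genes 4 of 17 fell, including Mvd with -0.86 ± 0.20 (camera adjusted p = 2.0e-04; adjusted p = 0.277 with an estimated correlation). Among adipocyte genes 0 of 19 passed (camera adjusted p = 0.126), and of the Notch pathway genes 1 of 15 rose (camera adjusted p = 6.0e-06; adjusted p = 0.188 with an estimated correlation). Krt8 (0.06 ± 0.37), Krt5 (0.72 ± 0.79), Krt14 (-0.90 ± 0.77) and Trp63 (0.70 ± 0.48) did not pass.

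In all, limma called 1815 genes, 681 higher and 1134 lower in the arrays labelled K8 tumor, of which 320 and 279 differed by at least 1 on the log2 scale. The count was 6341 with array weights, 2859 with only the groups compared, 2893 with the adipocyte mean as a covariate, 3963 without K8 tumor 9 and Lgr5 tumor 10 and 5351 without these and the arrays labelled Lgr5 tumors 2, 6, 7, 8 and 9. Without K8 gland 1 it was 30 and without K8 gland 2 it was 75, the remaining gland being assumed to vary like the other groups, while without K8 tumor 9 it was 3382.

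Between the tumor-gland contrasts, 269 genes were called higher in both and 665 lower in both, where independent lists of these sizes would share 35.9 and 120, and 0 were called in opposite directions. These contrasts share no arrays, only the pooled estimate of spread. The overlap was 1404 higher and 2384 lower with array weights, 0 and 0 with the adipocyte mean as a covariate, 0 and 1 without the arrays labelled Lgr5 tumors 2, 6, 7, 8 and 9, 891 and 1681 without K8 tumor 9 and Lgr5 tumor 10, and 1182 and 1777 without all 7. Without a single array it was 1 and 13 (K8 gland 1), 7 and 36 (K8 gland 2), 22 and 98 (Lgr5 gland 1), 83 and 184 (Lgr5 gland 3), 565 and 1185 (K8 tumor 9) or 529 and 1170 (Lgr5 tumor 10).

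The third comparison sets the tumors of the lines against each other (n = 10 and n = 10). All 19 adipocyte genes were lower in the arrays labelled K8 tumor than in those labelled Lgr5 tumor. Adipoq fell by 3.49 ± 0.71 (log2, SE; limma adjusted p = 0.0118), the lipid droplet genes Plin1 and Cidec fell by 3.18 ± 0.65 and by 3.09 ± 0.63, Lep fell by 3.19 ± 0.72 and Aqp7 fell by 3.27 ± 0.70 (camera adjusted p = 1.1e-15; adjusted p = 0.457 with an estimated correlation). Of the fatty acid synthesis genes 9 of 14 fell, including Fasn with -1.40 ± 0.34 (camera adjusted p = 9.6e-05; adjusted p = 0.457 with an estimated correlation). Of the cholesterol synthesis genes 8 of 17 fell, including Insig1 with -1.56 ± 0.39, and 1 rose (camera adjusted p = 1.6e-04; adjusted p = 0.457 with an estimated correlation). Of the brown adipocyte genes 3 of 10 fell (camera adjusted p = 4.2e-04; adjusted p = 0.457 with an estimated correlation). The adipocyte fall was largest against the 5 arrays labelled Lgr5 tumor whose means of that list were 12.59 or above. In the other 5 labelled Lgr5 tumor the mean was 9.58 to 11.13. In the arrays labelled K8 tumor it was 7.91 to 9.48, apart from 11.44 in K8 tumor 7.

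Cell cycle genes were higher in the arrays labelled K8 tumor, where 28 of 29 rose, including E2f8 with 0.86 ± 0.16 and Aurkb with 1.12 ± 0.25 (camera adjusted p = 1.1e-15; adjusted p = 0.457 with an estimated correlation). The list mean was at most 7.94 in the arrays labelled Lgr5 tumors 2, 6, 7, 8 and 9 and at least 8.10 in the other arrays labelled tumor. Of the epithelial and luminal keratin genes 13 of 18 rose, among them Epcam with 0.84 ± 0.23, Krt19 with 0.92 ± 0.26 and Krt8 with 0.73 ± 0.21 (camera adjusted p = 8.9e-07; adjusted p = 0.457 with an estimated correlation). Their list mean was at most 9.55 in those 5 arrays and higher in every other array labelled tumor. The direction of the epithelial list turned without these 5, K8 tumor 9 and Lgr5 tumor 10 (adjusted p = 0.741). Of the basal and myoepithelial genes 7 of 19 rose, among them Krt5 with 1.49 ± 0.46, the basal transcription factor gene Trp63 with 0.79 ± 0.27, Itga6 with 0.55 ± 0.15 and Lamb3 with 1.23 ± 0.37 (camera adjusted p = 1.1e-04; adjusted p = 0.457 with an estimated correlation). The basal mean was 8.53 to 9.33 in those 5 arrays, 9.41 to 10.60 in the others labelled Lgr5 tumor and 8.87 to 10.80 in those labelled K8 tumor. Of the milk and alveolar genes 5 of 18 rose, including Elf5 with 0.99 ± 0.26 (camera adjusted p = 0.0308; adjusted p = 0.547 with an estimated correlation). The direction of this list turned without the 5 arrays (adjusted p = 0.819) and without all 7 (0.31). Outside the lists the enamel matrix gene Amtn rose by 3.30 ± 0.80, the fibrinogen chain gene Fgb by 2.62 ± 0.81 and the carbonic anhydrase gene Car12 by 2.23 ± 0.77, the last with -0.27 without those 5 arrays.

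Lymphocyte genes were lower in the arrays labelled K8 tumor. Of the T cell genes 6 of 13 fell, including Cd3e with -0.81 ± 0.26 (camera adjusted p = 2.2e-05; adjusted p = 0.457 with an estimated correlation). Of the B and plasma cell genes 6 of 14 fell, including Cd79a with -1.24 ± 0.39 (camera adjusted p = 9.4e-05; adjusted p = 0.457 with an estimated correlation). The T cell mean was 7.08, 7.10 and 7.05 in Lgr5 tumors 2, 7 and 8. It was 6.72 and 6.60 in Lgr5 tumors 1 and 4, and 6.04 and 6.23 in Lgr5 tumors 6 and 9. Esr1 (0.00 ± 0.26), Pgr (0.94 ± 0.47), Lgr5 (-0.65 ± 0.53), Krt14 (1.08 ± 0.45) and Pik3ca (-0.03 ± 0.05) did not pass.

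In all, limma called 4246 genes, 2452 higher and 1794 lower in the arrays labelled K8 tumor, of which 174 and 342 differed by at least 1 on the log2 scale. limma called 7997 with array weights and 0 with the adipocyte mean as a covariate (512 at an unadjusted p under 0.05). Without the arrays labelled Lgr5 tumors 2, 6, 7, 8 and 9 it called 0 (1638 at an unadjusted p under 0.05), and without tumor 2, 6, 7 or 8 alone it called 2366, 2328, 2403 or 2291. The arrays labelled Lgr5 tumor were also more unlike each other, with a mean distance (1 minus Pearson's r of gene-centred values) of 0.978 against 0.679 among those labelled K8 tumor (permutation test, two-sided, p = 0.00347), a difference of -0.298 that became -0.11 (permutation test, p = 0.453) without those 5 arrays. Centring was on all arrays labelled tumor, so a difference between the group means can enter the distance and these p-values.

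**Figure D3:**
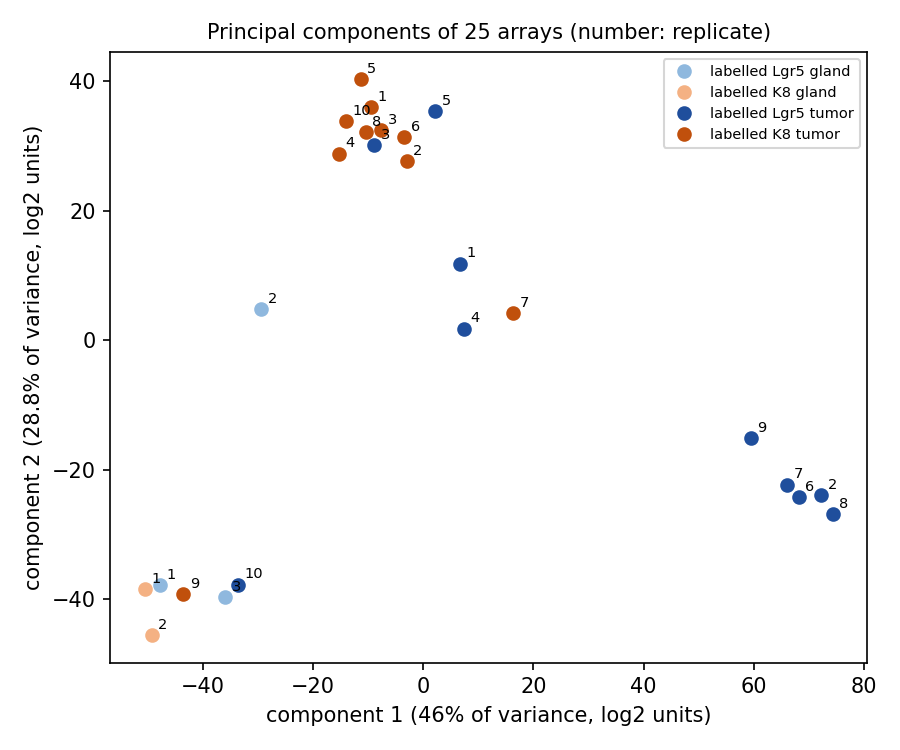
First principal component (horizontal axis, 46% of the variance) and second (vertical axis, 28.8%) of the 25 arrays over 19937 genes, in log2 units. Points are arrays, coloured by labelled group, with their replicate numbers. The arrays labelled Lgr5 tumors 2, 6, 7, 8 and 9 form a set of their own, and K8 tumor 9 and Lgr5 tumor 10 lie with 4 of the 5 arrays labelled gland.

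The reference glands of the lines were compared as a measure of line and background without the tumor. None of the genes the design is about passed between the arrays labelled K8 gland (n = 2) and Lgr5 gland (n = 3), with log2 differences of -0.05 ± 0.43 for Krt8, 0.42 ± 1.08 for Lgr5, -0.69 ± 0.54 for Esr1, -0.31 ± 0.95 for Pgr, -0.32 ± 0.93 for Krt5, 0.00 ± 0.91 for Krt14, -0.49 ± 0.56 for Trp63 and -0.04 ± 0.09 for Pik3ca (SE). Fibroblast and matrix genes shifted down as a list (camera adjusted p = 2.2e-08; adjusted p = 0.418 with an estimated correlation) and cell cycle genes shifted up (camera adjusted p = 1.2e-04; adjusted p = 0.673 with an estimated correlation), with 0 of 20 and 0 of 29 members past the gene test. limma called 0 genes, against 319 at an unadjusted p under 0.05, 5 with array weights, 3 without K8 gland 1 and 15 without K8 gland 2.

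The tumor-gland change itself was compared between lines. The difference, K8 minus Lgr5, was 0.78 ± 0.48 (log2, SE) for Krt8, 1.81 ± 1.04 for Krt5, 1.28 ± 0.62 for Trp63, 1.08 ± 1.02 for Krt14, 0.69 ± 0.60 for Esr1, 1.25 ± 1.06 for Pgr, -1.08 ± 1.20 for Lgr5 and 0.02 ± 0.11 for Pik3ca, and none passed. The adipocyte list shifted down (camera adjusted p = 1.5e-09; adjusted p = 0.502 with an estimated correlation) and the basal and myoepithelial list up (camera adjusted p = 2.5e-07; adjusted p = 0.502 with an estimated correlation), with 0 members of either past the gene test. limma called 0 genes, against 883 at an unadjusted p under 0.05, 0 with array weights, 3 without K8 gland 1 and 14 without K8 gland 2.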

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

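The tests of sample order, of fat tissue, of skin and of the removal of 5 arrays were chosen after the results they bear on were seen; the draws of other arrays and the splits of the arrays were planned before their outcome was known. Groups are named by label.

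The 5 arrays labelled gland had adipocyte means of 7.91 to 9.90 (log2), and those labelled Lgr5 tumors 2, 6, 7, 8 and 9 had 12.59 to 12.72. Fat tissue in those 5 tumors with all labels right stays open for those 5 arrays: it would dilute their epithelium, and their epithelial means were at most 9.55, below every other array labelled tumor, though arrays of another tissue could give this too. It does not address the other part of the pattern, the adipocyte means of 9.90 or below in the arrays labelled gland. Skin in the gland samples stays open. Of 12 measured epidermal and melanocyte markers, 9 never reached the median of all values of the genes tested (7.14). These 9 exclude nothing (median difference 0.15 over all 12). Among them, Krt77, Pmel and Krt78 peaked at 6.59, 6.46 and 6.45, above the highest array median over all probe sets (6.43). The count thus depends on the bound. Lce1a1, Lce1c and Cdsn, too few for a test by the bound used, were higher in arrays labelled gland by 3.11, 2.73 and 1.34 (median 2.73). They did not follow the gland label alone. Cdsn was highest in Lgr5 tumors 2 and 9 (10.21 and 10.17). Lce1a1 was 8.11 in K8 tumor 9, 8.32 in Lgr5 tumor 10 and 6.29 in Lgr5 gland 2. A candidate explanation is a value table laid out in text order of the sample codes in the labels (1, 10, 11 and so on) under labels in numeric order. That order puts the codes of the 5 glands on exactly those 5 arrays (5 of 5). From 25 arrays 53130 sets of 5 could be drawn, but this number overstates how unlikely the match is. Both sets are runs of adjacent samples, and text order moves the gland codes as a block. Splits of the arrays by probe sets with a high and a low state, leaving out those of markers already seen, do not separate the orders (3 of 7 in 1 line in either). They cannot decide, since the 3 under the labels are all sets of those same 5 arrays. Under the text-order hypothesis, formed after those 5 arrays were seen, 1 array keeps its own code and 4 keep their labelled group, so it would bear on every comparison.

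The genes called by limma between arrays labelled K8 tumor and Lgr5 tumor, 4246 in all, numbered 0 without the arrays labelled Lgr5 tumors 2, 6, 7, 8 and 9 (1638 at an unadjusted p under 0.05). Of 100 draws that leave out 5 arrays labelled Lgr5 tumor, 28 made 0 calls, that draw included, and all draws other than that one had a median of 2673 and a highest count of 9070. The 28 met the bound set beforehand for a smaller number of arrays as the cause, 5 or more of 100 draws. A count by how many of the 5 each draw left out was added later. By that count the 28 all left out at least 3 of the 5, and the 50 draws that left out at most 2 made 2555 to 9070. Every draw left out the same number of arrays, so these counts argue against the smaller number alone as the cause of 0 calls. The SE by itself does not settle the cause. Without the 5 its median was 0.924 of that with all arrays over the genes called, which were chosen with the 5 present. Over all genes it was 1.16, where the number alone gives 1.22. Whether the smaller number adds to the loss cannot be told here. Background strain, which goes with the line, stays open as untested.

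Random splits of the arrays tested whether chance gives as many calls, and splits that did were few in both comparisons below. They do not show that the labels are right, since another grouping that keeps like arrays together can also give many calls. For arrays labelled Lgr5 tumor and Lgr5 gland, 3 of 100 splits called at least as many genes as the real 3168, the real one included, with 5220 the highest of the others, which points to a structure of the samples besides the labels. For arrays labelled K8 tumor and Lgr5 tumor it was 1 of 100, with 4246 in the real split and 2986 as the highest of the others. The real split keeps the arrays labelled Lgr5 tumors 2, 6, 7, 8 and 9 together, and 0 genes were called without them.

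Among 186 sets of values of 10 arrays, 68 had an array far from the other 9 by Dixon's ratio, where chance gives about 1 in 20 and the sets are not independent. K8 tumor 9 stood apart in the list means of hormone-sensing luminal (7.91), squamous (8.61), neutrophil (6.96), endothelial (7.87), glycolysis and hypoxia (10.52), mesenchymal transition (8.71), Wnt response (8.11) and Notch pathway (8.02) genes. It also stood apart in Acta2 (10.37), Amtn (10.40), Cited1 (7.63), Cldn3 (11.26), Cnn1 (6.55), Crct1 (12.42), Cxcl2 (6.67), Dcn (12.06), Dpep1 (7.09), Elf5 (11.86), Esr1 (7.26), Fgb (6.57), Foxa1 (7.15), Klk6 (12.74), Klk7 (12.54), Krt1 (6.98), Krt16 (8.74), Krt6b (10.64), Krtdap (10.33), Myh11 (6.92), Olah (6.98), Pgr (5.84), S100a8 (10.06), S100a9 (8.49), Slc16a3 (9.84), Sprr1b (8.43), Tie1 (7.07) and Xbp1 (12.72). K8 tumor 7 stood apart in the list means of adipocyte (11.44), brown adipocyte (9.35), B and plasma cell (6.43) and fatty acid synthesis (11.54) genes and in Aqp7 (10.51), Cd79a (5.38), Ces1d (10.88), Fasn (12.98), Insig1 (10.97), Itga6 (11.16), Lep (9.44) and Plin1 (11.45). Lgr5 tumor 10 stood apart in the list means of squamous (9.00), neutrophil (7.79) and Wnt response (8.33) genes and in Cxcl2 (7.98), Dcn (12.60), Dpep1 (8.39), Esr1 (7.71), Foxa1 (7.77), Krt1 (7.79), Krt16 (9.74), Krt6b (12.08), Pik3ca (10.25), S100a8 (10.98), S100a9 (9.89), Slc16a3 (10.15), Sprr1b (10.23), Vwf (7.60) and Wap (8.52). Lgr5 tumor 5 stood apart in Ldha (12.44) and Lgr5 tumor 6 in Olah (6.09).

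The tumor-gland change differed between lines, by the test of the difference itself with camera, for 13 lists, none of which passed with an estimated correlation (lowest adjusted p = 0.502 with an estimated correlation). It was higher in the K8 line for hormone-sensing luminal (adjusted p = 0.0112), epithelial (3.1e-04), basal (2.5e-07), cell cycle (4.6e-05), Notch pathway (0.00372) and interferon response (0.0197) genes, and lower for adipocyte (1.5e-09), brown adipocyte (0.00936), T cell (0.00687), B and plasma cell (0.008), cholesterol synthesis (2.1e-05), fatty acid synthesis (6.1e-04) and glycolysis and hypoxia (0.0249) genes. The direction turned for epithelial genes without the arrays labelled Lgr5 tumors 2, 6, 7, 8 and 9 (0.171) and without these, K8 tumor 9 and Lgr5 tumor 10 (0.0261), and without all 7 for interferon response genes (0.616).

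Among 13120 probe sets without a single symbol, which the comparisons did not use, 461 were called for Lgr5 tumors against Lgr5 glands, 254 for K8 tumors against K8 glands and 924 for tumors against tumors when all probe sets were tested with limma.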

How the results depend on the processing

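Alternatives without the 5 arrays labelled Lgr5 tumors 2, 6, 7, 8 and 9, without K8 tumor 9 and Lgr5 tumor 10, without all 7, and with the adipocyte mean as a covariate (for counts and overlap) were added after seeing the data. Genes called in the Lgr5 tumor-gland contrast (3168, 33.2% higher) numbered 7815 (44.4% higher) with array weights, 690 with only the groups compared, 1 (Phb2, named after its value was seen) without the 5 arrays, 5387 without the 2, 3582 (39.8% higher) without the 7, 0 with the covariate, and 252 to 4990 with 1 array left out, 1976 and 705 of these without Lgr5 glands 2 and 3. In the K8 tumor-gland contrast (1815) they were 6341, 2859, 3963 without the 2, 5351 without the 7, 2893 with the covariate, and 30 to 3382. Between tumors (4246) they were 7997 with array weights, 0 without the 5, without the 7 and with the covariate, and 2291 to 5698; leaving out Lgr5 tumor 2, 6, 7 or 8 gave 2366, 2328, 2403 or 2291. Between glands (0) they were 5 (BC048679, Bex1, Odam, Rhoj and Scarna8, named after their values were seen) with array weights, 1 (Bex1) without the 2 or the 7, and 0 to 15; for the difference of contrasts (0) they were 1 (Bex1) without the 2 and 0 to 14.

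The replicate numbers showed no clear pairing of the samples, but few pairs under doubted labels cannot exclude one. Of 10 pairs of a K8 with an Lgr5 tumor, 4 had a correlation over 0.1 (-0.15 to 0.51). In 1 of these the K8 tumor correlated best with its own number. Of tumors paired with glands of their line, this held for 0 of 3 Lgr5 pairs (-0.37 to -0.044) and 1 of 2 K8 pairs (-0.0084 to 0.023). With the replicate number as a block (replicate block), 1737 genes were called in the Lgr5 tumor-gland contrast, and no other count of genes moved by over 1.5 times.

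Lists called (16, 15, 12, 14 and 13) were 0 with an estimated correlation in all 5 contrasts, and 11, 10, 9, 0 and 0 with fry, the zeros being between glands and for the difference. They were 5 between tumors with the covariate (0 higher and 5 lower, against 4 and 8, with 1 and 15 without the 5 and 2 and 13 without the 7). With 1 array left out they were 15 to 17, 14 to 15, 11 to 15, 9 to 15 and 11 to 16. Genes higher in both tumor-gland contrasts (269) were 1404 with array weights, 0 without the 5, 891 without the 2, 1182 without the 7, 0 with the covariate and 1 to 565 with 1 array left out. Genes lower in both (665) were 2384, 1, 1681, 1777, 0 and 13 to 1185. Genes with opposite calls (0) were 17 with array weights and 0 to 1. The difference in spread (-0.298) was -0.11 without the 5, -0.0672 without the 7 and -0.426 to -0.252 with 1 tumor left out.

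Directions turned, with these adjusted p, for lists between tumors without the 5 and the 7: milk (0.819 and 0.31), squamous (2.1e-04 and 0.0299), interferon (4.7e-04 and 7.5e-05), and epithelial without the 7 (0.741). For the difference of contrasts they were milk (0.0395 and 0.00668), epithelial (0.171 and 0.0261), endothelial (0.00792 and 2.1e-04), interferon without the 7 (0.616), and with 1 array left out milk (0.0288, range to 0.991) and neutrophil (0.00959, range 8.3e-04 to 0.912). Between glands they were neutrophil without dim genes (0.921), and with 1 array left out milk (0.89, range from 4.9e-08), squamous (0.22, range from 1.3e-04) and neutrophil (0.0403, range 4.2e-11 to 0.645). Car12 between tumors was -0.27 without the 5 and without the 7. The cause was not tested for any of these, except for the loss of calls between tumors without the 5. For that loss the draws of other arrays met the bound set beforehand for a smaller number of arrays. A count added later, by how many of the 5 each draw left out, argued against the smaller number alone. Background correction could not be varied, and signal over background was not analysed here.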

Other observations

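All tests in this part were chosen after the values were seen, as were the genes named in it.

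The albumin gene Alb was 9.92 to 10.30 (log2) in the arrays labelled Lgr5 tumors 2, 6, 7, 8 and 9 and at most 5.89 in every other array. Ucp1, the uncoupling protein of brown fat, was 12.47, 12.07 and 12.18 in those labelled Lgr5 tumors 6, 7 and 8, and 5.92 and 5.89 in those labelled 2 and 9. It was also 11.30 in K8 tumor 7, 10.00 and 9.49 in Lgr5 tumors 4 and 1, 8.10 in K8 tumor 3 and 7.37 in Lgr5 tumor 10. Cox8b, a respiratory chain gene of brown fat and muscle, was 11.43 to 12.97 in all 5 arrays labelled Lgr5 tumors 2, 6, 7, 8 and 9. It was also 12.49 in K8 tumor 7, 11.76 and 11.65 in Lgr5 tumors 4 and 1, and 10.03 in Lgr5 tumor 10. Skeletal muscle genes had list means of 10.01, 9.45 and 10.21 in K8 tumor 7 and Lgr5 tumors 1 and 4, and the muscle creatine kinase gene Ckm was 11.50, 11.07 and 11.65 there. The list means were 9.23 in Lgr5 tumor 10 and 8.36 and 8.04 in K8 tumors 8 and 3, with Ckm at 10.99, 10.28 and 9.85. In Lgr5 gland 3 the list mean was 7.90 and Ckm was 9.98. The inner root sheath keratin gene Krt25 was 10.08 in Lgr5 gland 3, 8.37 and 9.39 in K8 glands 1 and 2, and 8.65 in Lgr5 tumor 10. The defensin gene Defb4 was 8.99 to 9.79 in the arrays labelled gland other than Lgr5 gland 2 (5.39) and in K8 tumor 9 and Lgr5 tumor 10.

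A hypothesis is that the values sit under the wrong labels because the columns follow the sample codes in text order. It was tested on all 53 probe sets with a gap of at least 2 (log2) between a high and a low state, at least 3 arrays on each side and an SD under 0.6 on both, which make 10 different splits of the arrays. Of the 10, 6 had their smaller side in 1 line in text order and 4 under the labels. However, 3 of these splits are the arrays of the markers given below, which had already been seen to fall in 1 line in text order. Without those 3 it was 3 of 7 in either order (permutation test of the line labels, one-sided, p = 0.0702 for each). This tie cannot decide between the orders. Under the labels the 3 are all sets of the arrays labelled Lgr5 tumors 2, 6, 7, 8 and 9, which are the pattern to be explained. In text order they were the set of Lgr5 tumors 6, 7 and 8 and splits that hold arrays labelled gland. The idea was formed after the values, strain-like markers among them, had been seen.

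Of markers picked after text order had been seen to place each in 1 line, which makes them illustrations and no test, AI506816 was 9.05 to 10.08 in 5 arrays, labelled 1 K8 and 4 Lgr5, and 4.79 to 4.98 in the others. Apobec3 was 10.85 to 11.08 in 6 arrays, labelled 4 K8 and 2 Lgr5, and at most 10.20 in the others, a gap below the 2 asked of that screen. An unnamed probe set was 9.40 to 9.96 in 7 arrays, all labelled Lgr5, and at most 6.46 in the others. In text order the 5 and the 7 are K8 and the 6 are Lgr5. No comparison was rerun under that order.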
